A study of Saccharomyces cerevisiae with 310 samples.

How the data were processed

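The samples were 14 libraries of input chromatin from 1 yeast strain, 7 at 0 h and 7 at 6 h after galactose. Per the labels' protocols, cells grew in medium with 2% raffinose, were arrested with 5 µg/ml nocodazole, received 2% galactose to switch on AsiSI and were fixed with 1% formaldehyde for 16 min. Chromatin was sheared by sonication to 200 to 500 bp, and libraries were made from 1 to 3 ng of DNA with the Accel-NGS 1S Plus kit, which ligates adapters to single strands and so keeps strand identity, with 10 to 12 cycles of PCR.

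Reads were aligned to sacCer3 with Bowtie2 2.2.9 and handled with SAMtools, per the submitters' processing notes. The authors deposited for each sample 1 list of fragments on the forward strand and 1 on the reverse strand, each row giving the chromosome, start and end of 1 mapped fragment. Per the file contents these are positions only: nothing was counted, pooled or scaled, repeated positions were kept, and the score field is 0 throughout, so no filter on mapping quality could be applied. The names forward and reverse were taken as the strand of the sequenced molecule. If the lists give its complement, every statement here about which strand rose or fell turns round. Whether the authors removed any reads is not given in the sources used here. The lowest start in the lists lies 1 base below a usual BED start, so all starts were shifted by 1 before use. Chromosome names and lengths were checked against the reference genome R64, which has the same coordinates as sacCer3 and supplied sequence and annotation. The 2-micron plasmid was not analysed here.

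Depth was 4994940 to 9759617 fragments per sample, with median lengths of 184 to 217 bp. Repeats of a fragment with the same position and strand made up 2.79% to 32.5% of a sample. Fragments come from PCR without molecular identifiers, so they are not independent molecules, and statements on depth cover counting error only. Library size was the number of nuclear fragments outside the rDNA array, 2982611 to 6734151 per sample. Replicates were compared before they were averaged. In each group the 21 pairs of samples differed by more than counting noise, with chi-square per degree of freedom from 1.28 to 5.18 at 0 h and from 1.50 to 4.77 at 6 h. PCR copies also raise this value, so it cannot tell whether a pair should count as 1 sample, and all 14 were kept as samples. Nor does it show that the libraries came from separate cultures.

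Groups came from the labels alone. Of 310 samples in the series 296 were not used here, and 8 of these had labels that did not settle their group. The tests, gene lists, named-gene rule and the first set of alternatives were chosen before the data were examined. Everything described as chosen or added after seeing the data was not.

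AsiSI motifs were all 38 occurrences of the recognition sequence on the nuclear chromosomes. A fragment counted as spanning when it covered the whole 8 bp motif. Spanning fragments were scaled to CPM, fragments per 1000000 of the library size, and compared between 7 and 7 samples with a two-sided exact permutation test over all splits, whose smallest p is 0.000583, with Benjamini-Hochberg adjustment over motifs and a threshold of 0.05. Motifs with fewer than 20 spanning fragments over the 0 h samples were left out, which removed no AsiSI motif. The cut fraction of a sample at 6 h is 1 minus its spanning rate over the mean rate at 0 h, in percent. Near-cognate motifs had exactly 1 mismatch, and 11 palindromes with the bases of the motif in another order gave a second background. The strand ratio is the log2 ratio of fragments on the strand with its 5' end at the break to those on the other strand, from 0.1 to 5 kb on both flanks of the called motifs, and its reach was read in 40 bins of 1 kb, each flank ending midway to the next motif or at the chromosome end. Correlations across motifs used 100000 resamples.

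Genes and bins over 40 kb from every motif were tested for the number of fragments with their midpoint inside. Genes with at least 10 fragments per sample on average entered limma-voom with robust empirical Bayes moderation and Benjamini-Hochberg adjustment. Strand ratios per gene, log2((forward + 1)/(reverse + 1)), were tested with limma with a trend. Sets were tested with limma's fry, whose p asks whether the genes of a set move, on balance, one way and does not compare the set with other genes. The 9 lists were the GAL regulon, ribosomal proteins, glycolysis, DNA damage response, histones, heat shock and stress, gluconeogenesis and respiration, tRNA genes and Ty elements. Named items followed a fixed rule: the 5 motifs with the highest and the 5 with the lowest cut fraction, the 5 near-cognate motifs with the smallest p (with 37 tied, those with the largest loss), the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, the 5 largest changes of strand ratio each way, and from each list the 2 members with the largest change. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

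The tests of spanning fragments, of strand loss and its reach, of fragments per gene and of strand ratio per gene were tested on simulated data first. With known changes put into 4853 simulated genes, limma-voom for 6 h against 0 h recovered 45 of 50 genes changed 1.25-fold, 50 of 50 at 1.5-fold, 50 of 50 at 2-fold and 44 of 50 at 0.8-fold, with 12 false among 201 calls. The strand-ratio test recovered 19 of 50 genes at a log2 change of 0.3, 47 of 50 at 0.6, 28 of 50 at −0.3 and 42 of 50 at −0.6, with 8 false among 144 calls. Simulated genes were drawn independently of each other, and their strands with counting error only. They lacked the trends on gene length that the real samples carry, so these rates may not hold for the real data. For the comparison of spanning fragments at the 38 motifs, 1.43% of simulated uncut motifs were called lower and 3.57% higher, 15.7% of motifs with a simulated cut fraction of 10% were called lower, 55.8% at 20% and 100.0% at 40%.

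Alternatives included counting repeated fragments once, leaving out each replicate number in turn, other scalings and library sizes, other windows and count minimums, a test of same-numbered pairs, and removal of trends on GC content and gene length.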

Results

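DNA ends made by site-specific nucleases in budding yeast, Saccharomyces cerevisiae, were followed by sequencing sheared chromatin with a library method that keeps the strand of origin of each molecule. The series holds 310 samples, and 14 of them were analysed here. These 14 are input chromatin (sheared DNA taken without immunoprecipitation) of strain YSB958, in which galactose switches on AsiSI, a restriction enzyme that recognises GCGATCGC. Cells growing in raffinose were arrested in M phase with nocodazole, and 7 samples were taken at 0 h and 7 at 6 h after galactose was added. The labels state that these samples serve to measure how well AsiSI cut, and the strand-specific libraries also show where 1 strand was lost. The samples held 4994940 to 9759617 mapped fragments each and 87056677 together. The replicates are numbered 1 to 7, but nothing says that they came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. None of the 14 was kept for 6 h without galactose or without AsiSI. Away from the motifs, effects of galactose, of AsiSI breaks and of time or handling therefore cannot be told apart. The other 296 samples were not used here.

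At 6 h after galactose, fragments that run across AsiSI motifs were fewer at 25 of the 38 motifs in the nuclear genome and more numerous at 0 motifs. The sum over all 38 motifs went from 677 ± 25.6 spanning fragments per 1000000 nuclear fragments outside the rDNA (CPM) at 0 h to 438 ± 28.5 CPM at 6 h (SD, n = 7 each, exact permutation p = 0.000583, two-sided). This is a mean cut fraction of 35.3% ± 4.21 (SD, n = 7), with single samples between 26.6% and 39.9%. The motifs lie on 14 of the 16 nuclear chromosomes, and cutting ranged widely among them. The 25 called motifs lost 21% to 85.9% of their spanning fragments, 13 motifs lost more than 50%, and the 13 motifs past no threshold lay between −8.53% and 8.97%.

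The highest cut fraction was at chromosome VII 384683 to 384690, in the coding exon of PUS2, a pseudouridine synthase of mitochondrial tRNA. Spanning fragments there went from 17.8 ± 1.35 to 2.51 ± 1.67 CPM, a cut fraction of 85.9% ± 9.39 (SD, n = 7, exact permutation adjusted p = 0.00117, lower in 7 of 7 samples). The motif at X 391960 to 391967, in the coding exon of YJL027C and 436 bp from RNR2, which encodes a small subunit of ribonucleotide reductase, had a cut fraction of 84.9% ± 9.28. In the coding exon of IFM1, the mitochondrial translation initiation factor 2, the motif at XV 279289 to 279296 reached 82.2% ± 9.75. An intergenic motif at VII 12062 to 12069, 331 bp from VEL1 and 411 bp from MNT2, reached 76.3% ± 11.2. The motif at IX 291768 to 291775, 98 bp from BCY1, the regulatory subunit of protein kinase A, and 857 bp from ULP2, a SUMO protease, reached 73.6% ± 7.08. Each of these 4 motifs had the same exact permutation adjusted p of 0.00117 with n = 7. Coordinates are in sacCer3, counted from 1.

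The 5 lowest cut fractions did not differ from 0 by more than the spread between samples. They were −0.067% ± 12.2 at V 64446 to 64453 between PAU2 and TCA17, −5.12% ± 14.5 at XIII 138947 to 138954 between ITT1 and ERV41, and −5.33% ± 15.02 at X 175360 to 175367 in the coding exon of the potassium transporter gene TRK1. The other 2 were −5.68% ± 16.0 at IX 103511 to 103518 in the coding exon of ASG1 and −8.53% ± 17.3 at XVI 540043 to 540050 in the coding exon of CHL1, a helicase gene of sister chromatid cohesion. Exact permutation adjusted p lay between 0.367 and 0.995 for these 5 (n = 7). The motifs held 304 to 711 spanning fragments each over the 7 samples at 0 h.

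Fragments that ended just past a motif counted as uncut in this measure. When a spanning fragment also had to cover 25 more bases on each side, a setting chosen after seeing the data, the mean cut fraction was 47.5% ± 1.93 (SD, n = 7) and 29 motifs were called, among them all 25 of the main test. In this measure 10 motifs lost more than 80% of their fragments. Palindromes of the same bases in another order, all over 40 kb from an AsiSI motif, served as background. They lost 6.87% ± 3.61 of the fragments spanning their 8 bp (SD, n = 7, exact permutation p = 0.00524) and 8.01% ± 4.69 of those spanning 25 more bases on each side (SD, n = 7, exact permutation p = 0.00816).

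**Figure D1:**
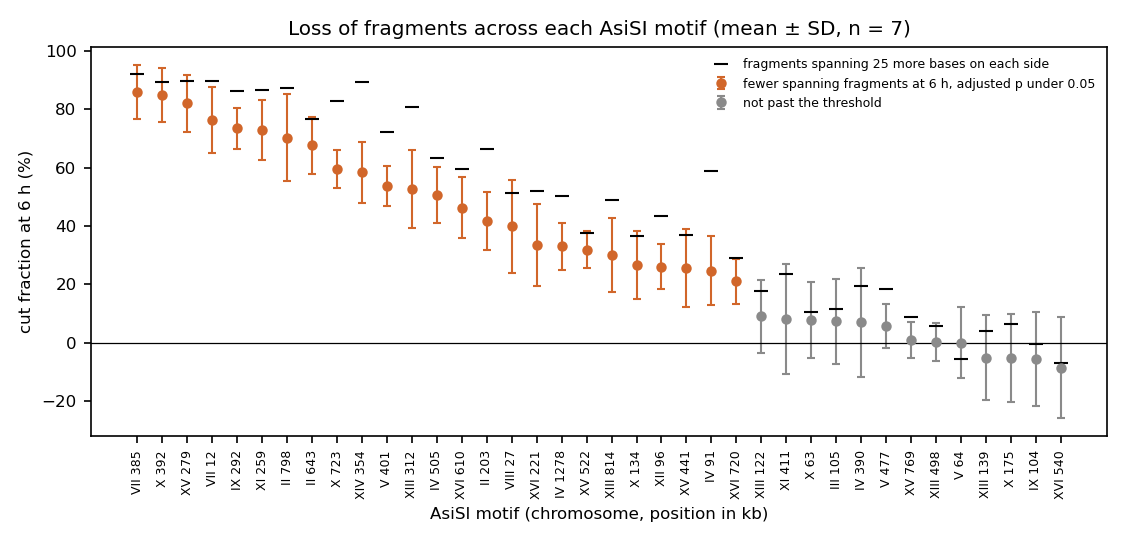
Cut fraction at 6 h in percent (vertical axis) for each of the 38 AsiSI motifs, ordered from highest to lowest and named by chromosome and position in kb (horizontal axis). Circles and bars are the mean and SD over 7 samples, orange for the 25 motifs past an adjusted p of 0.05 and grey for the other 13, and black dashes are the values when 25 more bases on each side had to be covered; the orange motifs run from 85.9% down to 21%.

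No gain of 5' ends in CPM was detectable at the base where AsiSI leaves them. Fragments that began within 1 base of that position numbered 148 over the 7 samples at 0 h and 192 at 6 h, or 5.53 ± 1.63 and 6.19 ± 1.61 CPM (SD, n = 7, exact permutation p = 0.452). The exact permutation test called 0 of the 38 motifs, and 3 had an unadjusted p under 0.05. The 3' ends of fragments did gather there. Within 15 bases of the cut position, a window chosen after seeing the data, 3' ends went from 87.8 ± 3.16 to 283 ± 43.4 CPM, 3.23-fold (SD, n = 7, exact permutation p = 0.000583). They rose at 36 motifs, all 25 called cut and 11 of the 13 others.

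Beside the cut motifs, the strand whose 5' end lies at the break was lost. In 50 flanks of the 25 called motifs, from 0.1 to 5 kb, this strand stood at 98.7% ± 0.787 of the opposite strand at 0 h and at 67.2% ± 5.71 at 6 h (SD, n = 7). On the log2 scale the ratio changed by −0.56, from −0.02 ± 0.01 to −0.58 ± 0.12 (SD, n = 7, exact permutation p = 0.000583). Fragments of the strand with the 5' end at the break went from 10086 ± 63.6 to 5215 ± 568 CPM, a change of −48.3%. The strand with the 3' end at the break changed by −24.0%, from 10217 ± 57.4 to 7762 ± 405 CPM (SD, n = 7, exact permutation p = 0.000583 for each strand). At the 13 motifs not called cut the log2 ratio changed by −0.06, from −0.06 ± 0.02 to −0.12 ± 0.02 (SD, n = 7, exact permutation p = 0.000583), in a comparison added after seeing the data.

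Strand loss was greatest next to the break and faded with distance. The log2 ratio changed by −0.91 in the first 1 kb, by −0.37 from 4 to 5 kb and by −0.10 from 11 to 12 kb. Every 1 kb bin from the break to 12 kb passed the adjusted threshold (exact permutation test, n = 7, adjusted over 40 bins), and the bin from 12 to 13 kb changed by −0.05 with an adjusted p of 0.0699. Beyond that point 1 of the remaining bins, from 23 to 24 kb, passed with a change of −0.03 (exact permutation adjusted p = 0.00897, n = 7).

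**Figure D2:**
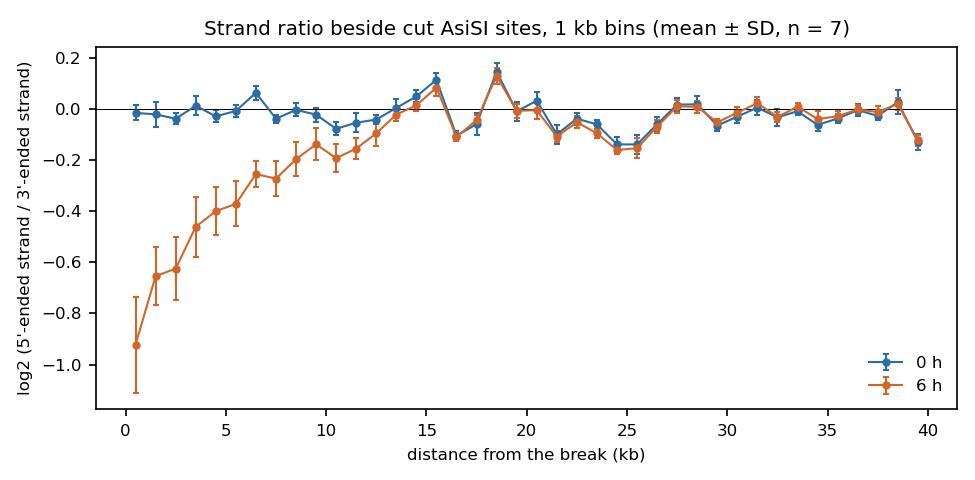
Log2 ratio of the strand with its 5' end at the break to the strand with its 3' end there (vertical axis) in 1 kb bins from 0 to 40 kb (horizontal axis), summed over the flanks of the 25 called motifs, as mean and SD over 7 samples at 0 h (blue) and 7 at 6 h (orange). The 6 h curve starts at −0.92 and meets the 0 h curve beyond about 12 kb.

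Motifs that lost more spanning fragments also lost more of the 5'-ended strand. Across the 38 motifs Spearman's rho was −0.909 and Pearson's r −0.889 (permutation p = 1e-05 for each, the smallest 100000 resamples can give), and r was −0.888 without the 2 motifs farthest from the median cut fraction. These motifs share the same samples and are not independent replicates. Strand loss passed the adjusted threshold at 31 motifs, including all 25 that were called cut. The motif in ASG1 was the 1 exception that passed in the other direction, with a log2 change of 0.06 (exact permutation adjusted p = 0.0041, n = 7). The annotation made no detectable difference to cutting. The 29 motifs in genes had a mean cut fraction of 34.7% and the 9 intergenic motifs 31.6%, with an exact permutation p of 0.784.

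Motifs with 1 mismatch to the AsiSI sequence lost spanning fragments at 85 sites, and the largest losses lay next to a true motif. Of 1234 such near-cognate motifs 1232 could be tested, and the exact permutation test called 3 higher. Within 10 kb of an AsiSI motif 28 of the 67 tested were called lower, at 10 to 40 kb 9 were, and at over 40 kb 48 of 981 were, the last with losses of 12.8% to 31.2%. Adjusted within each distance class alone, 34 of 67 near-cognate motifs and 32 of 52 palindromes within 10 kb were called lower, with summed losses of 25.4% ± 3.28 and 29.0% ± 2.87 (SD, n = 7), at 10 to 40 kb 0 of 184 and 7 of 107 were, and over 40 kb away 26 of 981 and 26 of 517 were. At 37 motifs p was the smallest the design allows, 0.000583, and the 5 of them with the largest loss all lay within 2 kb of an AsiSI motif. With substitutions counted from 1 at the 5' end of the AsiSI motif and its base given first, these were G3A at VII 10148 to 10155 (77.5% ± 5.85, 1914 bp from the motif near VEL1), C6A at VII 385009 to 385016 (71.8% ± 6.18, 326 bp from the motif in PUS2) and G3T at X 391607 to 391614 (71.2% ± 6.74, 353 bp from the motif in YJL027C). The other 2 were G3A at V 399273 to 399280 between SHO1 and AVT6 (63.6% ± 7.46) and T5A at XI 257492 to 257499 in MTC2 (59.0% ± 6.46), each with an exact permutation adjusted p of 0.0194 (n = 7). When 25 more bases on each side had to be covered, 0 of the 981 over 40 kb away were called, and 0 of 1222 near-cognate motifs gained or lost 3' ends. These tests, and those within distance classes, were added after seeing the data.

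Mitochondrial DNA fell and ribosomal DNA rose as shares of all fragments. The mitochondrial share was 31.3% ± 4.99 at 0 h and 17.6% ± 4.14 at 6 h, 0.562-fold, and every sample at 6 h lay below every sample at 0 h. The rDNA array, the tandem repeat of ribosomal RNA genes on chromosome XII (451786 to 468931), went from 7.29% ± 1.06 to 11.5% ± 1.04, 1.57-fold. For each share the exact permutation p was 0.000583 (n = 7). Against the other nuclear fragments alone the rDNA rose 1.37-fold.

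**Figure D3:**
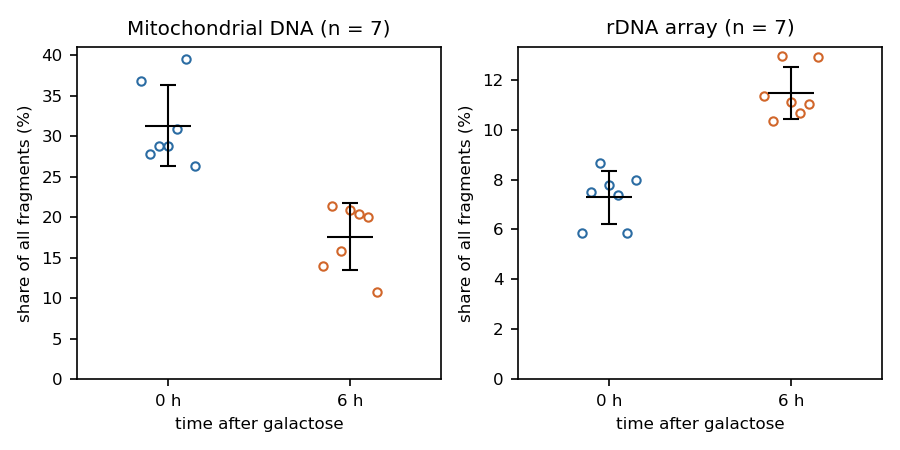
Share of all fragments in percent (vertical axes, starting at 0) from mitochondrial DNA (left) and the rDNA array (right) at 0 h and 6 h (horizontal axis). Each circle is 1 sample and the bars give mean and SD (n = 7); no 6 h sample overlaps the 0 h samples in either panel.

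Over 40 kb from every AsiSI motif, fragments from retrotransposons and from the galactose genes rose, and fragments from tRNA genes moved down as a set, though not past the threshold once the trend on gene length was removed. These are shares of sequenced DNA, not expression. Of 4853 genes tested with limma-voom 1229 changed, 975 up and 254 down (79.3% up). The split depended on the scaling: 298 genes rose and 308 fell after quantile normalization, 510 rose and 437 fell after scaling to the median of log ratios, and 55.2% of calls were rises after a trend on GC content was removed. The changes were small, with a median size of 0.16 on the log2 scale, and 145 rises and 101 falls exceeded 1.2-fold. They also followed gene length, with a Spearman correlation of 0.56 across genes, which are not independent replicates. Removing the trend on gene length, a setting chosen after seeing the data, left 535 changed genes, 300 up and 235 down, of which 401 were among the 1229.

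GAL7, which encodes galactose-1-phosphate uridyltransferase (II 274427 to 275527), was among the 10 largest rises, with 64.4 ± 4.92 CPM at 0 h and 107 ± 7.27 at 6 h, a log2 change of 0.74 ± 0.05 (SE, limma-voom adjusted p = 1.00e-22). The other 9 were Ty1 retrotransposon genes, whose near-identical copies share reads, so that single values are uncertain. The highest was YAR009C (I 160597 to 164187), with a log2 change of 0.76 ± 0.09 from 353 ± 16.7 to 607 ± 97.1 CPM (limma-voom adjusted p = 3.61e-05). YML039W and YOL103W-B followed with 0.68, YLR157C-B, YPL257W-B and YGR027W-B with 0.67, and YNL054W-B, YDR365W-B and YJR029W with 0.66. In all 10 genes each of the 7 samples at 6 h lay above every sample at 0 h. Outside Ty elements and rDNA, and chosen after their values were seen, the seripauperin gene PAU9 (0.64 ± 0.20), its relative PAU20 (0.46 ± 0.11) and CHA1 (0.42 ± 0.06), the catabolic serine and threonine deaminase, also rose past the limma-voom threshold. PAU9 averaged 16.9 fragments per sample, near the minimum of 10, and 2 of its 7 samples at 6 h lay above every sample at 0 h. For PAU20 and for CHA1 5 of 7 did.

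The 10 largest falls were of genes shorter than 360 bp. They include 7 tRNA genes, YNCO0005W (−0.63 ± 0.15), YNCG0046W (−0.62 ± 0.14), SUF1 (−0.56 ± 0.16), YNCF0005C (−0.55 ± 0.13), YNCD0020W (−0.50 ± 0.15), SUF10 (−0.49 ± 0.16) and YNCN0012C (−0.49 ± 0.14). The 3 protein-coding genes were YHR007C-A (−0.53 ± 0.10), YMR082C (−0.47 ± 0.07) and CMC4 (−0.47 ± 0.08). With the trend on gene length removed, SUF1, YNCD0020W, SUF10 and YNCN0012C were no longer called, with limma-voom adjusted p of 0.106, 0.155, 0.197 and 0.164, and the other 6 still were. Removing the trend on GC content instead also cost SUF1, YNCD0020W, SUF10 and YNCN0012C their call (limma-voom adjusted p = 0.0519, 0.0943, 0.406 and 0.107).

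The galactose regulon rose as a group. Of its 9 listed genes 5 lay far enough from a motif to be tested, and all 5 rose, also when adjusted over the list alone, with a median log2 change of 0.56. They were GAL7 and the galactokinase gene GAL1 (0.59 ± 0.05, from 102 ± 4.14 to 154 ± 14.2 CPM), the permease gene GAL2 (0.56 ± 0.05), the epimerase gene GAL10 (0.47 ± 0.04) and MTH1 (0.14 ± 0.05), a negative regulator of glucose sensing. As a set they moved up (limma's fry, adjusted p = 1.13e-07 over 9 lists). Without the length trend 4 of the 5 stayed called and MTH1 did not (adjusted p = 0.169).

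The lists of gluconeogenesis and respiration, of glycolysis and of ribosomal protein genes moved down on balance, and in each a minority of genes fell past the threshold. Of 19 tested genes of the gluconeogenesis and respiration list 3 fell and 0 rose, and 3 fell when adjusted over the list alone (median −0.02, fry adjusted p = 0.0103). The fallers were HXT7 (−0.38 ± 0.04, from 188 ± 13.3 to 145 ± 10.6 CPM) and HXT6 (−0.34 ± 0.04), neighbouring and nearly identical genes of high-affinity hexose transporters whose reads cannot be fully separated, and QCR2 (−0.16 ± 0.05), a subunit of the respiratory cytochrome bc1 complex. Without the length trend 5 fell (median −0.07, fry adjusted p = 0.000332), these 3 and, named after their values were seen, ATP1 and JEN1 (limma adjusted p = 0.00453 and 0.00244). In glycolysis 5 of 14 fell and 2 rose, the same counts when adjusted over the list alone (median −0.07, fry adjusted p = 0.0113). GPM1, phosphoglycerate mutase, changed by −0.21 ± 0.06, ENO2, enolase, by −0.17 ± 0.05, and TPI1, TDH3 and FBA1 by −0.15, −0.15 and −0.14, whereas the phosphofructokinase genes PFK1 and PFK2 rose by 0.13 and 0.12. Without the length trend 4 fell and 0 rose: GPM1, ENO2 and FBA1 stayed called, and PDC1, named after its value was seen, was added (limma adjusted p = 0.0260). PFK1 and PFK2 went to 0.02 each (limma adjusted p = 0.728 and 0.819), whereas TPI1 and TDH3 kept changes of −0.14 and −0.17 but missed the threshold (limma adjusted p = 0.0735 and 0.0700). Of 101 ribosomal protein genes 11 fell, among them RPS28A (−0.34 ± 0.10), and 1 rose, with 9 falls and 0 rises when adjusted over the list alone (median −0.07, fry adjusted p = 0.0103). Without the length trend 6 fell, and RPS28A was not among them (limma adjusted p = 0.112). RPL29 had a log2 change of −0.28 ± 0.11 (limma-voom adjusted p = 0.0592). The medians of these 3 lists stayed negative under every scaling tried.

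The lists of DNA damage, heat shock and tRNA genes moved as sets, but none of the 3 passed fry once the length trend was removed, and histone genes passed in neither case. Of 12 DNA damage response genes 3 rose, the nucleotide excision repair gene RAD16 (0.18 ± 0.04), the ribonucleotide reductase gene RNR4 (0.17 ± 0.05) and the recombination gene RAD54 (0.10 ± 0.04), and PLM2 fell (−0.13 ± 0.04), with 3 and 1 when adjusted over the list alone. Their median was 0.07 (fry adjusted p = 0.0103), but −0.0037 after quantile normalization, and fry gave an adjusted p of 0.592 without the length trend, where RAD16 and RAD54 lost their call (limma adjusted p = 0.112 and 0.992). Of 10 heat shock and stress genes the heat shock protein genes HSP12 (0.24 ± 0.08) and HSP26 (0.22 ± 0.06) rose and 0 fell, with 2 rises when adjusted over the list alone. The median of 0.06 (fry adjusted p = 0.0181) turned to −0.0063 after quantile normalization and to −0.01 without the length trend, where the adjusted p was 0.856. In that last setting 2 genes of the list rose and 1 fell. None of 6 histone genes passed limma-voom, adjusted over the list alone or over all genes (median −0.06, and 0.01 after quantile normalization; fry adjusted p = 0.0609, and 0.554 without the length trend). HTB1 stood at −0.18 ± 0.08 and HHF1 at 0.10 ± 0.09. Of 190 tRNA genes 22 fell and 0 rose, 11 when adjusted over the list alone, with a median of −0.20 (fry adjusted p = 0.00177). Without the length trend 3 tRNA genes fell, the median was −0.02 and the adjusted p was 0.447. The median was −0.05 after quantile normalization and −0.08 with the GC trend removed.

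Genes inside Ty retrotransposons also rose as a group. Of 80 tested 67 rose and 0 fell, and 70 rose when adjusted over the list alone, with a median of 0.31 (fry adjusted p = 0.000104). Without the length trend 39 rose and 0 fell, with a median of 0.27 (fry adjusted p = 0.00616), and after quantile normalization the median was 0.19.

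**Figure D4:**
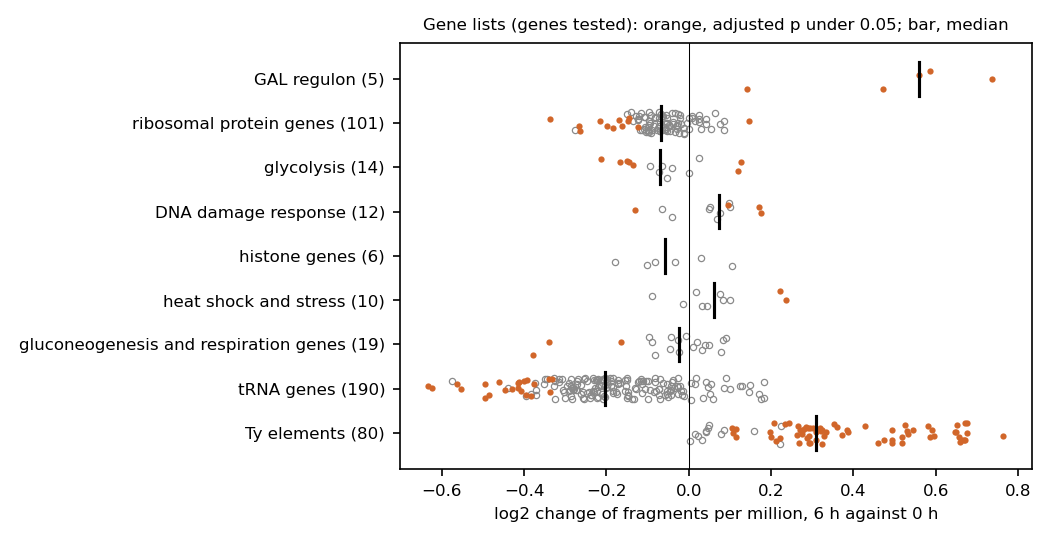
Log2 change of CPM at 6 h against 0 h (horizontal axis) for the tested genes of each list (vertical axis, number tested in brackets). Points are genes, orange where the limma-voom adjusted p is under 0.05, and black bars are list medians, from −0.20 for tRNA genes to 0.56 for the GAL regulon; the medians of the DNA damage, histone and heat shock lists change sign after quantile normalization.

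The ratio between strands also changed away from AsiSI motifs, and nearly all genes where this happened lie in Ty elements. The forward to reverse ratio changed at 57 of 4853 genes, 28 up and 29 down, and 55 of the 57 lie in Ty elements. Near-identical Ty copies share reads, so these 55 are not independent of each other. At all 55 the change was toward the strand that serves as template for transcription, the minus strand of the element. The largest were YOL103W-A (−0.96 ± 0.12, SE, on the log2 scale), YGR027W-A (−0.87 ± 0.11), YLR256W-A (−0.83 ± 0.10), YPL257W-A (−0.81 ± 0.10) and YDR365W-A (−0.80 ± 0.11) among falls of forward over reverse, and YNL284C-A (0.81 ± 0.13), YPR137C-A (0.80 ± 0.10), YPR158C-C (0.74 ± 0.10) and YAR010C (0.68 ± 0.09) among rises. Limma's adjusted p was at most 0.00129 for these 9 genes. Toward the template did not mean toward equality everywhere. At these 9 the strands were closer to equal at 6 h, as at YGR027W-A, where the log2 ratio went from 0.86 ± 0.11 to −0.0086 ± 0.30 (SD, n = 7). At other called Ty genes they were less equal at 6 h, as at YML039W, an example chosen after seeing its values, with 0.05 ± 0.05 at 0 h and −0.56 ± 0.21 at 6 h (SD, n = 7). The remaining 2 of the 57, singled out after seeing their values, were YLR035C-A, annotated as a Ty gag-pol gene (0.42, limma adjusted p = 0.024), and RPL29 (0.67 ± 0.14, limma adjusted p = 0.0225). With genes in Ty elements and rDNA left out of the limma test, chosen after seeing the data, 0 genes passed, and 293 of all tested genes had an unadjusted p under 0.05. Among all genes, near motifs or not, 194 changed, and 122 of these were among the 426 genes within 10 kb of a motif.

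Over 40 kb from AsiSI motifs, the share of 1 kb bins that rose was largest in rDNA, then in Ty elements, then near centromeres. Of 9192 bins tested with limma-voom 1841 rose and 1325 fell. Bins that overlap Ty elements rose in 219 of 259 cases and fell in 0, with a median log2 change of 0.42, and all 18 rDNA bins rose, with a median of 0.47. Within 20 kb of a centromere 187 of 446 bins rose and 25 fell, with a median of 0.10. In the last 20 kb of chromosome arms 102 of 552 rose and 81 fell (median 0.02), and among the 7944 bins in none of these classes 1335 rose and 1219 fell (median 0.01).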

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

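None of the tests in this part was chosen after its result was seen. Of 23 groups of 7 values checked for a sample that stands apart from the rest, 5 held one, where chance picks about 1 in 20. Replicate 3 at 6 h kept the most spanning fragments over the AsiSI motifs, 497 CPM. Replicate 2 at 0 h had the highest strand ratio beside the called motifs, 0.0051 on the log2 scale, and the highest percentage of repeated fragments, 32.5%. Replicate 5 was the most deeply sequenced at both times, with 8868027 fragments at 0 h and 9759617 at 6 h. No biological explanation was tested for these 5 values.

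Whether chance could give the counts was asked with 100 splits of the 14 samples into 7 and 7, the real one included. Only 1 of 100 splits, the real one, gave as many changed sites, genes or bins in 6 comparisons. Such counts are therefore unusual among splits of these samples. As the samples may be technical, this does not exclude chance differences between cultures or preparations. The real count and the highest other were 25 and 22 for AsiSI motifs with fewer spanning fragments, 88 and 0 for near-cognate motifs, 13 and 1 for bins with strand loss, 1229 and 542 for genes, 57 and 1 for genes with a changed strand ratio, and 3166 and 1153 for 1 kb bins. For 5' ends at the break the real count was 0 and the highest other 1. All 100 of 100 splits give at least 0, so this count says nothing about chance.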

How the results depend on the processing

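The comparisons added only after the results were seen were those with 25 more bases, scaling by palindromes, 3' ends, motifs not called, near-cognate motifs over 40 kb away, shares with pairs or with repeats counted once, gene length, and genes without Ty elements and rDNA. Of 118 alternatives over 13 results, 98 of them fixed before the data were examined, 106 kept the direction and the side of the threshold, or a count within 1.5 times, 12 moved a count further and 0 reversed. Some of the 106 could not differ. Other count minimums left the same AsiSI motifs, and the library size cancels in the strand ratio. The mean loss of spanning fragments stayed between 27.7% (scaled by the retained strand) and 47.5% (25 more bases), and its motif count between 22 and 29. Leaving out each replicate number in turn gave 23 to 25 motifs, 33.9% to 36.9% mean loss, −0.59 to −0.53 for the strand ratio, 12 to 13 kb of reach (13 without replicate 7), 962 to 1229 genes and 55 to 58 genes with a changed strand ratio. Same-numbered samples correlated weakly over 4853 genes, from 0.0020 to 0.144, 1 of 7 over 0.1. The mean was 0.063 for equal numbers and −0.011 for unequal ones. Of the 7 samples at each time, 3 at 0 h and 4 at 6 h correlated best with their own number. A weak pairing is therefore not excluded, and the main tests do not use it. With the replicate number as a block 24 motifs, a mean loss of 35.1%, 1357 genes, 57 genes with a changed strand ratio and 3338 bins were called, the histone list reached a fry adjusted p of 0.0398 and RPL29's strand ratio lost its call (adjusted p 0.197). The block left 0 near-cognate motifs, because too few of them reached its smallest p of 0.0156 for that p to pass the adjustment. Near-cognate counts were 47 with 25 more bases, 26 over 40 kb away (0 there with 25 more bases) and 24 scaled by palindromes (with 10 higher, against 3 in the test as reported), where the one over 40 kb away tests fewer sites and the cause of the others was not tested. Sites with new ends numbered 36 for 3' ends, another measure by construction. Genes changed numbered 1929 with genes near motifs included, which tests more genes, and 606 after quantile normalization (cause not tested) and 535 with the length trend removed, which takes out the changes that follow length. Genes with a changed strand ratio numbered 194 with genes near motifs and 0 without genes in Ty elements or rDNA. Of the 57, 55 lie in Ty elements, and the other 2 lost their call in that test, for a reason that was not examined. Bins numbered 733 at 5 kb, where fewer bins are tested. A minimum mapping quality of 20 was not run because the score field is 0 throughout. Depth limits single motifs: on simulated data 15.7% of motifs with a 10% loss were called.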

Other observations

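The promoter, centromere and Ty family comparisons, and for the explanations below the tests of PCR copies for Ty1 and for mitochondrial DNA, of gene length and of reverse transcripts for Ty1 and of GC content for the GAL genes, were chosen only after the results were seen; the others were not.

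Sheared chromatin held more DNA from promoters than from gene bodies, and less so at 6 h than at 0 h. Over 1663 protein-coding genes of at least 1500 bp, fragments from −400 to 0 relative to the start of the gene exceeded those from 500 to 1000 by 0.63 ± 0.03 on the log2 scale at 0 h and by 0.36 ± 0.09 at 6 h (SD, n = 7, exact permutation p = 0.000583), or 1.54-fold and 1.28-fold. The upstream part changed by −0.15 and the body by 0.12. Regions near centromeres gained in the same samples. Outside Ty elements and rDNA and over 40 kb from AsiSI motifs, bins within 20 kb of a centromere held fragments equal to 5.04% ± 0.0848 of those in other bins at 0 h and 5.35% ± 0.0771 at 6 h (SD, n = 7, exact permutation p = 0.000583). The gain was positive on all 13 chromosomes with at least 10 such bins, and 12 passed the exact permutation test after adjustment, chromosome II (0.02, adjusted p = 0.146) being the exception. Of 254 genes within 20 kb of a centromere 114 rose and 9 fell, and 79 rose and 7 fell with the length trend removed.

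Ty families rose to different extents, with all copies of a family summed because they share reads. In 28 of the 31 annotated Ty1 elements, those far enough from motifs, minus-strand fragments went from 8315 ± 366 to 14816 ± 3033 CPM, 1.78-fold, and plus-strand fragments from 8678 ± 283 to 11223 ± 1096, 1.29-fold (SD, n = 7, exact permutation adjusted p = 0.00117 over 10 tests for each). Ty2 rose by 0.27 on the minus and 0.15 on the plus strand, Ty5 by 0.35 and 0.27, Ty3 by 0.07 and 0.09 and Ty4 by 0.08 and 0.10 on the log2 scale, all past an exact permutation adjusted p of 0.05. With repeated fragments counted once Ty1, Ty5 and the minus strand of Ty2 stayed past it, but the plus strand of Ty2 (0.115), both strands of Ty3 (0.148 plus, 0.225 minus) and both of Ty4 (0.194 plus, 0.532 minus) did not. The ratio of minus to plus changed by 0.44 in Ty1 (exact permutation adjusted p = 0.00291) and by 0.12 in Ty2 (0.00874), and in Ty3, Ty4 and Ty5 the adjusted p lay between 0.341 and 0.601. Along 27 full-length Ty1 elements divided into 10 parts the minus-strand gain was largest in the sixth part, 1.05, and smallest in the second, 0.44.

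The rise of minus-strand Ty1 DNA was weighed against technical explanations. Counting repeated fragments once left a log2 change of 0.77. Ty1 copies share reads, so repeats of 1 molecule may be listed at different copies and escape this count. It lowered minus-strand fragments at 0 h from 218077 to 213184 in Ty1, and from 1955 to 1741 in Ty5, which has 1 annotated element. PCR copies are therefore not excluded. The median change of genes in Ty elements, over both strands and all families, was 0.27 with the length trend removed. Gene length is thus excluded as the whole cause of the rise of these genes, but the minus strand of Ty1 alone was not tested. Base composition predicted a shift toward the minus strand of 0.012 where the 55 Ty1 genes had a median of 0.61. Composition is excluded as the whole cause of that shift. A hypothesis is that part of the minus-strand Ty1 DNA may be reverse transcripts of Ty1 RNA. Their synthesis is primed near the 5' LTR and, after a strand transfer, runs on from the 3' end, so incomplete products would favour the 3' part, and the ratio of the part 3' of the midpoint to the part 5' of it rose by 0.17 on the minus strand (exact permutation p = 0.000583, n = 7). The plus strand shifted by 0.19 in the same way, so this test does not decide, and the hypothesis stays open, as do copies that differ from the reference.

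The rise of the GAL genes was weighed against copy number, GC content and PCR. The 38 other genes within 20 kb of GAL1, GAL7, GAL10 or GAL2 had a median change of 0.11 (18 rose and 0 fell) where the GAL list had 0.56. The GAL median was 0.53 with the GC trend removed and 0.56 with repeated fragments counted once. GC content, PCR copies and a copy-number gain over the whole 20 kb around these genes are therefore each excluded as the whole cause. A gain limited to the GAL genes and their closest neighbours was not tested. The nearest neighbour, SRL2 at 458 bp, rose by 0.37, and the next nearest, KAP104, FUR4 and EMP46, by 0.18, 0.14 and 0.18. A candidate explanation that stays open, and was not tested, is that chromatin of strongly transcribed genes shears or dissolves more easily.

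The fall of the mitochondrial share could not be told apart from a change in how evenly the libraries sample the genome. Within groups the share rose with the promoter excess at 6 h (Pearson's r = 0.913, rho = 0.857, exact permutation p = 0.00278 and 0.0238, adjusted over 4 relations 0.0111 and 0.0952, r = 0.767 without the 2 farthest samples). At 0 h the relation was weaker (r = 0.630, rho = 0.429, exact permutation p = 0.142 and 0.354, n = 7) and rests on 2 samples, without which r was −0.197. The pooled slope predicts a change of −12.7 percentage points (SE 3.75) where −13.7 was observed, which keeps this explanation open. The 7 mitochondrial windows of at least 30% GC fell 0.80 times as much on the log2 scale (bootstrap SE 0.0313) as the 61 windows under 15% GC. This is 1 to 2 SE above the bound of 0.75 set beforehand, so it argues against GC bias as the whole cause without excluding it. Counting repeated fragments once left a change of −13.0 points, so PCR copies are excluded as the whole cause. The fall still followed GC over 171 windows (Spearman 0.592), so GC stays open as part of it. Fewer mitochondrial genomes per cell after 6 h also stay open and were not tested.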
